A study of Arabidopsis thaliana with 12 samples.

How the data were processed

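Gene expression was measured by RNA sequencing in Arabidopsis thaliana Col-0 lines that stably expressed green fluorescent protein (GFP) alone, called Control, or GFP fused to 1 of 2 candidate secreted effectors of the poplar rust fungus Melampsora larici-populina, called Mlp37347 and Mlp124499. Each of the 3 groups had 4 libraries, and each library was made from pooled aerial tissue of soil-grown plants 15 days after germination, under 16 h of light per day at 22 °C. The labels do not say whether the 4 libraries of a line came from separately grown batches of plants, so the p-values measure the spread between these samples, part of which may be technical.

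Per the labels' protocols, libraries were made with the TruSeq Stranded mRNA kit on a NeoPrep instrument from 100 ng of total RNA. They were sequenced as pairs of 100 nt reads on a HiSeq 4000, per the series' design text. Reads were trimmed with Trimmomatic and aligned to TAIR10 with TopHat 2.0.14, with the mate inner distance set for each library, per the series' design text and the submitters' processing notes. The deposited counts are whole numbers of read pairs overlapping each Ensembl Plants transcript locus, made by the authors in R 3.2.5 with GenomicAlignments in union mode, per the series' design text. Whether strand was used and how reads with several alignments were handled are not given in the sources used here. Values of near-identical genes (LHCB1, PDF1.2, CBF, KIN, COR15 and RBCS families) and of loci that overlap or lie antisense to others are therefore uncertain. A further deposited table gives the numbers of raw, surviving and aligned reads as counts and the mate inner distance in bp for each library. The count table holds 32833 loci, of which 285 are organelle loci with 0 counts in every library, and 99.1% of its identifiers matched locus tags of the TAIR10.1 annotation. That annotation was used only for gene names, exon lengths and GC content, and no coordinates are given because the deposited counts carry none.

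Total counts were 6645703 to 37378917 in Control, 12368262 to 24483245 in Mlp37347 and 10813288 to 14733894 in Mlp124499. No pair of libraries of a group was identical or within sampling noise of each other (chi-square per degree of freedom at least 2.82). Mlp37347 1, 2 and 3 were much closer to each other (2.82 to 6.27) than to Mlp37347 4 (154 to 208). Mlp124499 1 and 2 were at 6.94, against 40.6 to 132 in the other pairs of that line. Libraries this close may not be independent replicates. Counts were scaled by TMM in edgeR 4.0.16 under R 4.3.3, and 19090 genes passed filterByExpr on the 3 groups. All 12 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest) with 1 coefficient per group and no covariate. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and every adjusted p of a gene is from this edgeR test. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Expression levels are TMM-scaled counts per 1000000 counts of a library (CPM), given as mean ± SD over the 4 libraries of a group, computed here from the deposited counts.

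The 21 gene lists covered immunity, hormone responses, photosynthesis, the circadian clock, secondary metabolism, stress, nutrients, cell cycle, senescence, plasmodesmata, touch, root and flower markers, and 2 sets of reference genes. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation and with fry. Only pattern-triggered immunity in Mlp124499 against Control, 1 of the 27 list calls, held with an estimated correlation, and 14 of the 27 were past the threshold with fry, which tests whether a list's genes move one way on balance. Counts of list members refer to members tested. Members were counted over all genes tested and adjusted over the list alone. For reference genes the coefficient of variation (CV, SD divided by mean) over 12 libraries was compared with 10000 random lists matched on expression in 20 bins. Low-CV genes were chosen as the lowest 0.5% in libraries numbered 1 and 2 and scored in those numbered 3 and 4, and the other way round.

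The groups, tests, lists, other settings to be tried and the rule for named genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest fold changes per effector comparison, and the 5 highest and 5 lowest of the direct one, among genes past the threshold with at least 1 CPM on average and no overlap between groups. It added up to 3 members per list, every reference gene and the 5 genes of at least 10 CPM with the lowest CV. The other settings were other scalings and filters, DESeq2 1.42.0, limma voom with sample weights, a replicate block, a second threshold of 0.01, a tested fold of 1.5 and leaving out each library. Chosen after seeing the data were fits without both effector libraries numbered 4, fits without Control 1 and Mlp124499 3, the first components of the clock list as covariates and the mate inner distance as a covariate. Leaving out libraries for the lists, and leaving out Control 1 with Mlp124499 3 for the CVs, were added then as well.

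The fit was tested on simulated counts of 18781 genes with 200 genes changed. It recovered 6% of 2-fold and 92% of 4-fold changes in Mlp37347 against Control, 16% and 80% in Mlp124499 against Control, and 21% and 89% between the effector lines. False calls numbered 0, 2 and 7. Intervals and floors of low counts (3 counts over a group) cover counting error only.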

Results

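The data compared seedlings carrying either rust effector fusion with seedlings carrying GFP alone, and the series title states the choice of reference genes as the purpose. Of 32833 loci, 19090 were tested. Total counts were 6645703, 15082516, 14144272 and 37378917 in Control 1 to 4. They were 24483245, 20371132, 12368262 and 13892501 in Mlp37347 1 to 4, and 10813288, 11844380, 13144950 and 14733894 in Mlp124499 1 to 4. Control 1 had 57.6% of its surviving reads aligned, against 88.0% to 95.5% in the other libraries. The mate inner distance was 110 to 115 bp in Mlp37347 1, 2 and 3 and 50 to 84 bp in all others, with 70 bp in Mlp37347 4. The libraries with the long distance belonged to 1 group and gave no value within that batch.

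Libraries of both effector lines differed among themselves in clock and cold genes. PRR5 (AT5G24470), a clock repressor, stood at 40.4, 62.3 and 40.7 CPM in Mlp37347 1, 2 and 3 and at 192 CPM in Mlp37347 4. In Mlp124499 it stood at 59.2 to 64.3 CPM in libraries 1, 2 and 3 and at 1.75 CPM in library 4, within the Control range of 0.470 to 2.41 CPM. COR15A (AT2G42540), a cold-induced chloroplast protein, stood at 787 to 1999 CPM in Mlp124499 1, 2 and 3 and at 187 CPM in Mlp124499 4.

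**Figure D1:**
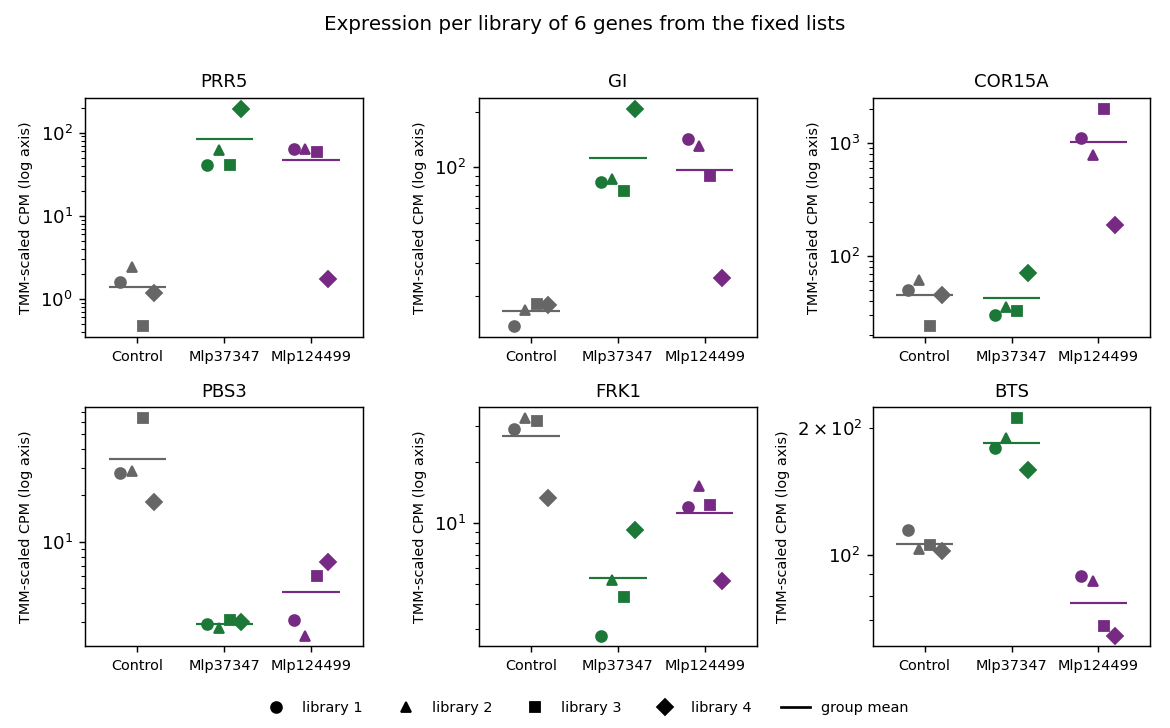
TMM-scaled CPM (log axis) of 6 genes in each of the 12 libraries, with symbols for the library number and a line for the group mean. PRR5 was at 1.75 CPM in Mlp124499 4 and at 59.2 CPM or more in the other Mlp124499 libraries, while PBS3 was at or below 7.39 CPM in all 8 effector libraries and at or above 18.1 CPM in Control.

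In the line with Mlp37347, genes of salicylic acid defence and of pattern-triggered immunity were lower than in Control. PBS3 (AT5G13320), an enzyme of salicylic acid synthesis, fell from 34.5 ± 19.9 to 2.94 ± 0.153 CPM (SD, n = 4), a log2 fold change of -3.55 ± 0.43 (SE, edgeR adjusted p = 0.0011). The immune regulators WRKY70 (AT3G56400, log2 fold change -2.37 ± 0.34, edgeR adjusted p = 0.0019) and EDS1 (AT3G48090, -1.51 ± 0.22, adjusted p = 0.0020) fell too. Of 23 salicylic acid genes 14 fell and 0 rose, with 17 lower when adjusted over the list alone. The camera adjusted p was 2.87e-12, and adjusted p = 0.327 with an estimated correlation. Of 25 pattern-triggered immunity genes 10 fell and 0 rose, 12 when adjusted over the list alone. For pattern-triggered immunity camera gave adjusted p = 1.94e-05, and adjusted p = 0.286 with an estimated correlation. They included FRK1 (AT2G19190), a receptor-like kinase induced by bacterial flagellin, from 26.8 ± 9.13 to 5.40 ± 2.74 CPM (log2 fold change -2.32 ± 0.42, edgeR adjusted p = 0.0064), NHL10 (AT2G35980, -3.01 ± 0.51) and WRKY53 (AT4G23810, -1.86 ± 0.29). Control 4 had the lowest mean level of the salicylic acid list among Control libraries, -0.97 on the log2 scale against the Control mean, and Mlp37347 4 had -2.65 against -1.64 to -1.39 in the other Mlp37347 libraries. Among jasmonate and ethylene genes 3 rose and 6 fell of 29, 4 and 10 when adjusted over the list alone (camera adjusted p = 0.277), and the list was not called. The defensin gene PDF1.2A (AT5G44420), among those that fell, was at 35.5 ± 18.9 CPM in Control and 1.67 ± 1.27 in Mlp37347 (log2 fold change -4.47 ± 0.62, edgeR adjusted p = 0.0017). Numbers past the threshold with Control 1 to 4, Mlp37347 1 to 4 and Mlp124499 1 to 4 left out in turn, or without the library named, were as follows. Salicylic acid genes gave 9 lower without Mlp37347 1. Pattern-triggered immunity genes gave 2 higher without Mlp37347 4, and 7, 7, 4, 9, 3, 3, 4, 12, 9, 8, 10 and 11 lower. Jasmonate and ethylene genes gave 0, 0, 0, 1, 0, 0, 0, 4, 3, 3, 3 and 3 higher, and 3, 2, 2, 7, 2, 3, 2, 8, 4, 3, 4 and 6 lower.

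Clock genes moved in both directions in Mlp37347, and chloroplast, iron and auxin genes also changed. Of 23 clock genes 8 rose and 5 fell, 11 and 6 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.404). PRR5 rose from 1.41 ± 0.810 to 83.9 ± 72.8 CPM (log2 fold change 5.91, edgeR adjusted p = 0.0045). So did LUX (AT3G46640), a component of the evening complex, from 4.72 ± 1.64 to 25.4 ± 7.06 CPM (2.45 ± 0.39), CHE (AT5G08330, 1.12 ± 0.16) and the RNA-binding protein gene GRP7 (AT2G21660, 3.59 ± 0.67). FKF1 (AT1G68050), a light sensor of flowering time, had 3 counts over the 4 Control libraries and 549 over the 4 Mlp37347 libraries, a ratio of 212 (95% counting interval 72.2 to 1031). Its value in Mlp37347 4 was 35.1 CPM against 2.07 to 3.41 CPM in the others, and its call was lost without Control 2, Control 3 or Control 4 (adjusted p = 0.0577, 0.0598 and 0.0658, within 1.05e-05 to 0.997 over all alternatives). PORB (AT4G27440), an enzyme of chlorophyll synthesis, rose from 167 ± 40.7 to 1841 ± 731 CPM (log2 fold change 3.47 ± 0.49). Photosynthesis genes were higher as a list, with 4 of 37 higher and 0 lower, 14 when adjusted over the list alone. Their mean, on the log2 scale against the Control mean, was -0.64 in Control 1 and 0.13 to 0.26 in Control 2, 3 and 4. It was 0.73 to 0.76 in Mlp37347 1, 2 and 3 and 0.34 in Mlp37347 4. For photosynthesis genes camera gave adjusted p = 9.99e-11, and adjusted p = 0.361 with an estimated correlation. BTS (AT3G18290), an iron-binding E3 ligase, rose from 106 ± 5.75 to 184 ± 21.5 CPM (log2 fold change 0.79 ± 0.17, edgeR adjusted p = 0.0135). Of 15 iron genes 4 rose and 0 fell, 6 when adjusted over the list alone. For iron genes camera gave adjusted p = 0.0013, and adjusted p = 0.327 with an estimated correlation. PIN3 (AT1G70940), an auxin efflux carrier, fell (log2 fold change -1.31 ± 0.23, edgeR adjusted p = 0.0051), and 4 of 19 auxin genes fell with 0 higher, 7 when adjusted over the list alone. For auxin genes camera gave adjusted p = 2.03e-06, and adjusted p = 0.361 with an estimated correlation. The auxin and iron means of Mlp37347 4 were 0.01 and -0.05, near Control, against -1.70 to -1.47 and 1.44 to 1.67 in Mlp37347 1, 2 and 3. Numbers past the threshold with Control 1 to 4, Mlp37347 1 to 4 and Mlp124499 1 to 4 left out in turn, or without the library named, were as follows. Clock genes gave 5 higher without Control 2 or Control 3, and 3, 3, 2, 5, 1, 1, 1, 10, 5, 5, 6 and 6 lower. Photosynthesis genes gave 3, 1, 0, 4, 0, 0, 0, 15, 3, 4, 4 and 9 higher. Iron genes gave 2, 1, 1, 6, 1, 1, 1, 10, 3, 3, 5 and 5 higher, and 2 lower without Mlp37347 4. Auxin genes gave 3, 2, 2, 2, 1, 1, 1, 13, 3, 3, 5 and 4 lower.

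Stress and growth lists differed as well in Mlp37347. Of 10 heat shock genes 4 fell and 0 rose, 7 when adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.452 with an estimated correlation), with the chaperone gene HSP90.1 (AT5G52640) at 40.4 ± 19.2 CPM in Control and 5.31 ± 0.845 CPM in the line (log2 fold change -2.91 ± 0.46, edgeR adjusted p = 0.0032). BIP3 (AT1G09080), a chaperone of the endoplasmic reticulum, fell (-3.12 ± 0.59) among 3 of 17 ER folding genes that fell, with 3 lower and 1 higher when adjusted over the list alone (list camera adjusted p = 0.387). Cell cycle genes had 2 of 16 higher and 0 lower, 4 when adjusted over the list alone. For cell cycle genes camera gave adjusted p = 4.42e-05, and adjusted p = 0.471 with an estimated correlation. Senescence genes had 2 of 9 lower, 3 when adjusted over the list alone. For senescence genes camera gave adjusted p = 0.0022, and adjusted p = 0.361 with an estimated correlation. The touch list was called lower with 1 of 14 members past the threshold, also 1 when adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.567 with an estimated correlation), and the call was lost without Control 1, Mlp37347 1 or Mlp37347 3 (adjusted p = 0.112, 0.0585 and 0.120, within 0.0011 to 0.712 over all alternatives). MYB51 (AT1G18570), a regulator of indolic glucosinolates, fell from 53.3 ± 13.4 to 20.14 ± 0.857 CPM (log2 fold change -1.40 ± 0.18, edgeR adjusted p = 0.0012), the 1 of 26 glucosinolate genes past the threshold, also 1 when adjusted over the list alone (list camera adjusted p = 0.553). The median log2 fold change of that list was 0.44 and its mean 0.45, while the camera test pointed lower, and without Mlp37347 4 it was called higher (adjusted p = 1.71e-04, within 6.50e-10 to 0.939 over all alternatives). CALS8 (AT3G14570), a callose synthase, fell (-1.73 ± 0.35), the 1 of 22 plasmodesmata genes past the threshold, also 1 when adjusted over the list alone (list camera adjusted p = 0.723). The cell cycle and senescence means of Mlp37347 4 were -0.30 and -0.05, against 1.12 to 1.14 and -1.98 to -1.69 in Mlp37347 1, 2 and 3. Lists without a call were cold and drought (3 of 27 higher, camera adjusted p = 0.179), flavonoids (1 of 18 lower, 0.903), root markers (1 of 2 higher, 0.404) and flower markers (1 of 5 lower, 0.404), with the same numbers when adjusted over the list alone, and phosphate (0.880). Numbers past the threshold with Control 1 to 4, Mlp37347 1 to 4 and Mlp124499 1 to 4 left out in turn, or without the library named, were as follows. Heat shock genes gave 3, 2, 2, 4, 1, 1, 1, 4, 5, 4, 4 and 6 lower. ER folding genes gave 2 higher without Mlp37347 4 and 1 higher without Mlp124499 4, and 1, 2, 1, 3, 2, 1, 1, 3, 3, 2, 3 and 3 lower. Cell cycle genes gave 0, 0, 0, 1, 0, 0, 0, 13, 2, 1, 2 and 2 higher. Senescence genes gave 1, 1, 0, 1, 0, 0, 1, 7, 1, 1, 2 and 1 lower. Touch genes gave 0, 0, 0, 1, 0, 2, 0, 2, 1, 1, 1 and 1 lower. Glucosinolate genes gave 13 higher without Mlp37347 4, and 2 lower without Mlp124499 4. Plasmodesmata genes gave 3 higher without Mlp37347 4 and 1 higher without Mlp124499 3, and 2 lower without Mlp37347 4. Cold and drought genes gave 1, 0, 0, 0, 2, 0, 2, 2, 1, 1, 2 and 5 higher, and 2 lower without Mlp37347 4. Flavonoid genes gave 7 higher without Mlp37347 4, and 1, 0, 0, 0, 0, 0, 0, 2, 1, 1, 1 and 2 lower. Root marker genes gave 0, 0, 0, 1, 0, 0, 0, 1, 1, 1, 1 and 1 higher. Flower marker genes gave 1, 1, 1, 0, 0, 0, 0, 1, 1, 1, 1 and 1 lower. Phosphate genes gave 3 higher without Mlp37347 4 and 1 higher without Mlp124499 3 or Mlp124499 4, and 1 lower without Mlp37347 4.

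Across all genes, 609 were higher and 1035 lower in Mlp37347 than in Control, and 1469 of these 1644 had no overlap between the 4 libraries of each group. Of all tested genes 19.2% had no such overlap, where chance gives 2.86%. AT4G34950 was at 138 to 173 CPM in Mlp37347 and at 11.5 to 17.1 CPM in Control (log2 fold change 3.42 ± 0.33, edgeR adjusted p = 4.73e-04). AT1G75945 had 2 counts over the 4 Mlp37347 libraries and 691 over Control, a ratio of 298 (95% counting interval 82.2 to 2467). The loci AT4G06665, AT2G08915, AT5G22505 and AT3G16525 were past the threshold as well. Control 1 held 56.7, 33.7, 21.0 and 90.5 CPM of them, more than any other library, and without it their adjusted p was 0.0594, 0.192, 0.0574 and 0.0800. The 4 calls were also lost without Mlp37347 1, 2 or 3 (adjusted p = 0.0701 to 0.109), and that of AT2G08915 without Mlp124499 1 (0.0530). Over all alternatives these values lay between 6.70e-05 and 0.997. Higher genes made up 37.0% of the calls, and 15.6% with total-count scaling, 10.1% with scaling by traditional reference genes and 24.8% with scaling by array-selected ones, which moved the median of all genes by -0.20, -0.40 and -0.08 on the log2 scale. The counts moved with single libraries. Without Mlp37347 4, 2245 genes were higher and 2158 lower, and 1073 were higher without Mlp124499 4. From 222 to 392 were higher without Control 1, 2 or 3 or Mlp37347 1, 2 or 3, and 401 to 557 were lower without Control 2 or 3 or Mlp37347 1, 2 or 3. With the mate inner distance as a covariate the counts were 172 and 106. Only Mlp37347 1, 2 and 3 had 110 to 115 bp, so that fit cannot separate the distance from the line.

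In the line with Mlp124499, immune genes were again lower than in Control, and cold and drought genes were higher. COR15A rose from 45.2 ± 15.8 to 1018 ± 756 CPM (log2 fold change 4.49 ± 0.63, edgeR adjusted p = 0.0038) and COR15B (AT2G42530) from 4.13 ± 2.88 to 423 ± 380.0 CPM (6.74 ± 0.93, adjusted p = 0.0037). Of 27 cold and drought genes 10 rose and 0 fell, 22 when adjusted over the list alone (camera adjusted p = 4.94e-18; adjusted p = 0.266 with an estimated correlation), and ERD7 (AT2G17840), induced early in dehydration, was among them (2.65 ± 0.46). The mean of this list in Mlp124499 4 was 1.07, against 2.82 to 3.80 in Mlp124499 1, 2 and 3. Mlp37347 4 stood at 2.65. PBS3 fell to 4.72 ± 2.34 CPM (log2 fold change -2.86 ± 0.41, edgeR adjusted p = 0.0043), with EDS5 (AT4G39030), a transporter of a salicylic acid precursor (-2.35 ± 0.38), and the transcription factor gene SARD1 (AT1G73805, -2.09 ± 0.34). Of 23 salicylic acid genes 13 fell and 0 rose, 19 when adjusted over the list alone. For salicylic acid genes camera gave adjusted p = 2.65e-16, and adjusted p = 0.265 with an estimated correlation. Of 25 pattern-triggered immunity genes 9 fell and 0 rose, 19 when adjusted over the list alone. For pattern-triggered immunity camera gave adjusted p = 8.28e-13, and adjusted p = 0.0177 with an estimated correlation. They included SOBIR1 (AT2G31880), a receptor-like kinase, from 123 ± 30.0 to 47.3 ± 4.79 CPM (log2 fold change -1.38 ± 0.21, edgeR adjusted p = 0.0053) and WRKY40 (AT1G80840, -2.08 ± 0.33). Of 23 clock genes 6 rose and 0 fell, 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0135; adjusted p = 0.532 with an estimated correlation), with GI (AT1G22770, 2.54 ± 0.48), GRP7 (4.40 ± 0.69) and ELF4 (AT2G40080, 5.01 ± 0.91) all nearest to Control in Mlp124499 4. Numbers past the threshold with Control 1 to 4, Mlp37347 1 to 4 and Mlp124499 1 to 4 left out in turn, or without the library named, were as follows. Cold and drought genes gave 5, 4, 3, 5, 11, 10, 10, 22, 5, 5, 5 and 20 higher. Salicylic acid genes gave 6 lower without Control 3 and 4 lower without Mlp124499 1 or Mlp124499 2. Pattern-triggered immunity genes gave 4, 5, 4, 9, 4, 5, 4, 12, 4, 2, 6 and 9 lower. Clock genes gave 3 higher without Control 3, and 1 lower without Mlp37347 4 and 4 lower without Mlp124499 4.

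Further lists were called between Mlp124499 and Control, though in some of them single libraries lay within the Control range. On the log2 scale against the Control mean, Mlp124499 4 stood at 0.23 for heat shock (Control -0.62 to 0.47). Mlp124499 3 stood at -0.17 for senescence (-0.45 to 0.31), and Mlp124499 3 and 4 at -0.04 and -0.41 for ER folding (-0.44 to 0.29). Jasmonate and touch means of all Mlp124499 libraries lay below Control. Of 29 jasmonate and ethylene genes 3 fell and 0 rose, 9 lower and 1 higher when adjusted over the list alone. For jasmonate and ethylene genes camera gave adjusted p = 0.0015, and adjusted p = 0.374 with an estimated correlation. Touch genes had 2 of 14 lower, 7 when adjusted over the list alone. For touch genes camera gave adjusted p = 2.89e-06, and adjusted p = 0.265 with an estimated correlation. Senescence genes had 2 of 9 lower, 4 when adjusted over the list alone (camera adjusted p = 0.0096; adjusted p = 0.484 with an estimated correlation), and the list call was lost without Mlp124499 4 (adjusted p = 0.0805, within 5.22e-05 to 0.484 over all alternatives). Photosynthesis and auxin genes were higher as lists with 0 of 37 and 0 of 19 members past the threshold, also 0 when adjusted over the list alone (camera adjusted p = 1.69e-05 and 0.0053; adjusted p = 0.484 and 0.531 with an estimated correlation). Photosynthesis means were -0.64 in Control 1, 0.13 to 0.26 in Control 2, 3 and 4 and 0.19 to 0.50 in Mlp124499, a range that overlapped with that of Control 2, 3 and 4. Auxin means were 0.49 to 0.79 in Mlp124499 1, 2 and 3 and 0.05 in Mlp124499 4, within the Control range of -0.19 to 0.10. At an unadjusted p under 0.05, edgeR had 9 photosynthesis genes higher and 1 lower, and 3 auxin genes higher. DESeq2 called 3 and 1 higher, and voom 15 higher and 6 lower for photosynthesis and 12 higher for auxin. The auxin call was lost without Mlp124499 3 (adjusted p = 0.0818, within 4.72e-04 to 0.667 over all alternatives). Heat shock genes had 1 of 10 lower and ER folding genes 0 of 17, also 1 and 0 when adjusted over the list alone (camera adjusted p = 0.0118 and 0.0118; adjusted p = 0.484 and 0.536 with an estimated correlation). Of the ER genes 3 were lower at an unadjusted p under 0.05 in edgeR, 2 by DESeq2 and 14 by voom, which also called 1 higher. Without Control 1 the list values became 0.0576 and 0.0831, the heat shock call was also lost without Control 3 (0.0576) or Mlp124499 1 (0.0547), and the ER call without Mlp124499 2 (0.0658) or Mlp124499 4 (0.0573). Over all alternatives they ranged over 6.54e-04 to 0.484 and 8.14e-04 to 0.536. Lists without a call were glucosinolates (1 of 26 lower, also 1 when adjusted over the list alone, camera adjusted p = 0.0550), flavonoids (0.139), cell cycle (0.139), plasmodesmata (0.320), iron (0.318), phosphate (0.101), root markers (0.525) and flower markers (1 of 5 lower, also 1 when adjusted over the list alone, 0.155). MYB51 fell (-1.20 ± 0.18, edgeR adjusted p = 0.0049). Numbers past the threshold with Control 1 to 4, Mlp37347 1 to 4 and Mlp124499 1 to 4 left out in turn, or without the library named, were as follows. Jasmonate and ethylene genes gave 1 higher without Mlp124499 4, and 2, 1, 0, 5, 2, 3, 2, 7, 0, 0, 0 and 7 lower. Touch genes gave 0, 0, 0, 1, 1, 3, 1, 6, 0, 0, 0 and 6 lower. Senescence genes gave 1, 1, 0, 3, 2, 2, 2, 3, 0, 0, 1 and 2 lower. Photosynthesis genes gave 1 higher without Mlp37347 4 or Mlp124499 4, and 4 lower without Mlp124499 4. Auxin genes gave 3 higher without Mlp37347 4. Heat shock genes gave 0, 0, 0, 1, 0, 0, 0, 1, 0, 0, 0 and 3 lower. ER folding genes gave 2 lower without Control 4 and 1 lower without Mlp37347 4. Glucosinolate genes gave 2 lower without Mlp124499 4.

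Across all genes, 297 were higher and 518 lower in Mlp124499 than in Control, and 708 of these 815 had no overlap between libraries, as did 10.95% of all tested genes against 2.86% by chance. CML42 (AT4G20780), a calmodulin-like protein, fell from 8.82 ± 1.71 to 0.151 ± 0.109 CPM (log2 fold change -5.77 ± 0.52, edgeR adjusted p = 6.67e-04). FT (AT1G65480), the mobile flowering signal, had 3 counts over the 4 Mlp124499 libraries and 136 over Control, a ratio of 30.5 (95% counting interval 10.2 to 149.5). AT2G01422 had 0 counts in all Control and Mlp37347 libraries and 300 over the 4 Mlp124499 libraries, at least 149-fold higher than the Control floor of 3 counts over the group. Its call against Control was lost without Mlp124499 2 (adjusted p = 0.0513, within 4.50e-09 to 0.0513 over all alternatives). Higher genes made up 36.4% of the calls and 16.0% with scaling by traditional reference genes, which moved the median of all genes by -0.34 on the log2 scale. These counts moved with single libraries too. Without Mlp124499 4, 793 were higher and 1085 lower, and without Mlp37347 4 729 and 829. From 89 to 179 were higher without Control 1, 2 or 3 or Mlp124499 1, 2 or 3, and 148 to 286 were lower without Control 2 or 3 or Mlp124499 1, 2 or 3. Without Control 1 and Mlp124499 3 together the counts were 88 and 165.

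**Figure D2:**
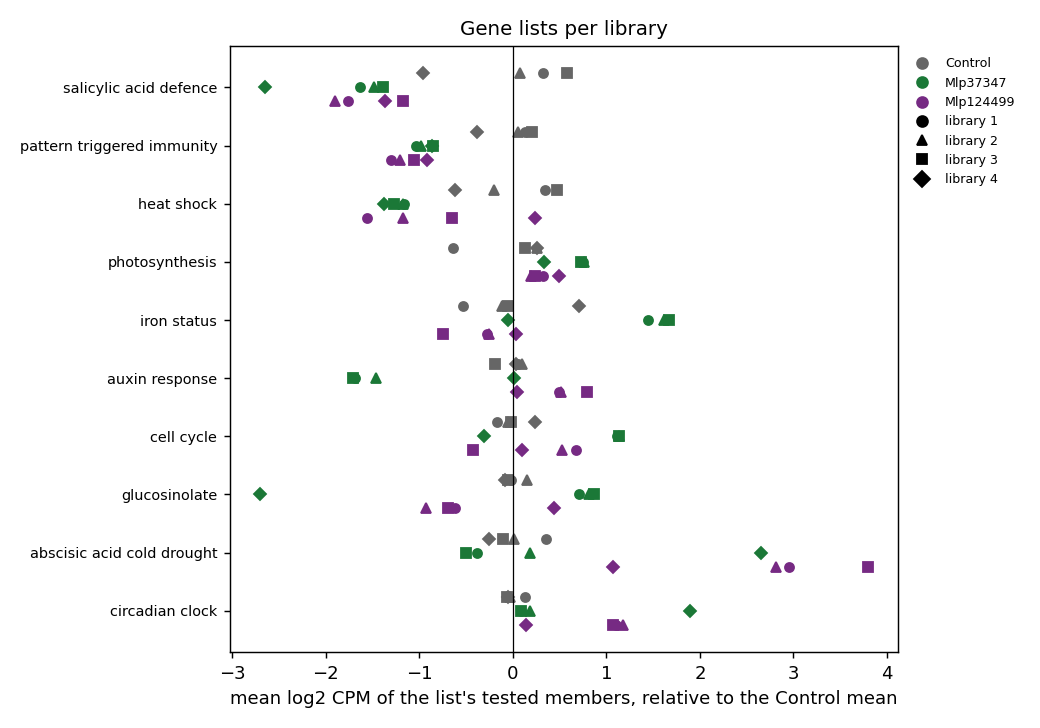
Mean log2 CPM of the tested members of 10 gene lists in each library, relative to the Control mean, with colour for the group and symbol for the library number. The salicylic acid list lay between -2.65 and -1.18 in the 8 effector libraries and between -0.97 and 0.57 in Control.

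The effector lines also differed from each other, in auxin, iron and cold genes. SAUR10 (AT2G18010), an auxin-induced gene, stood at 1.09 ± 0.485 CPM in Mlp37347 and 4.89 ± 1.24 CPM in Mlp124499 (log2 fold change -2.17 ± 0.32, edgeR adjusted p = 0.0042), and YUC9 (AT1G04180), an enzyme of auxin synthesis, was lower in Mlp37347 as well (-2.30 ± 0.34). Of 19 auxin genes 5 were lower in Mlp37347 and 0 higher, 15 when adjusted over the list alone. For auxin genes camera gave adjusted p = 2.24e-14, and adjusted p = 0.205 with an estimated correlation. BTS (1.26 ± 0.17, edgeR adjusted p = 0.0030) and the iron reductase gene FRO3 (AT1G23020, 1.08 ± 0.17) were higher in Mlp37347, among 5 of 15 iron genes higher and 0 lower, 10 when adjusted over the list alone. For iron genes camera gave adjusted p = 4.68e-05, and adjusted p = 0.205 with an estimated correlation. Cold and drought genes had 4 of 27 lower in Mlp37347, 8 when adjusted over the list alone, with COR15A at -4.59 ± 0.63. For cold and drought genes camera gave adjusted p = 5.30e-13, and adjusted p = 0.643 with an estimated correlation. In the auxin, iron and cold lists Mlp37347 4 stood at 0.01, -0.05 and 2.65 and Mlp124499 4 at 0.05, 0.03 and 1.07, on the log2 scale against the Control mean. Photosynthesis and cell cycle lists were higher in Mlp37347 with 0 members past the threshold, also 0 when adjusted over the list alone (camera adjusted p = 8.52e-04 and 0.0012; adjusted p = 0.712 and 0.712 with an estimated correlation). In these 2 lists Mlp37347 4 stood at 0.34 and -0.30, against 0.73 to 0.76 and 1.12 to 1.14 in Mlp37347 1, 2 and 3 and 0.19 to 0.50 and -0.42 to 0.68 in Mlp124499. At an unadjusted p under 0.05, edgeR had 6 genes of each of these lists higher, DESeq2 called 2 and 1 higher, and voom 20 higher and 1 lower for photosynthesis and 13 higher for cell cycle. NRT1.8 (AT4G21680), a nitrate transporter, was at 20.9 ± 4.74 CPM in Mlp37347 and 1.75 ± 2.25 CPM in Mlp124499 (3.53 ± 0.62), and PIL1 (AT2G46970), a shade-induced transcription factor gene, at 1.96 ± 2.19 and 33.6 ± 12.02 CPM (-4.17 ± 0.55). No difference was called for the salicylic acid list (camera adjusted p = 0.369) or pattern-triggered immunity (0.190), though the glutaredoxin gene GRXS13 (AT1G03850) was higher in Mlp37347 (1.52 ± 0.25, edgeR adjusted p = 0.0080). Median, mean and test differed in sign for senescence (median log2 fold change 0.21, mean -0.25, camera adjusted p = 0.369) and phosphate (0.12, -0.10, 0.271). In all, 210 genes were higher and 303 lower, and 10.9% of tested genes had no overlap. Higher genes made up 40.9% of calls and 18.8% with total-count scaling, which moved the median by -0.14. With only the 8 libraries of these lines the counts were 51 and 105. Without Mlp37347 4 they were 1407 and 1395, and 407 were higher without Mlp124499 4. Without any 1 of Control 2 or 3 or the other effector libraries they were 62 to 121 and 87 to 198. Numbers past the threshold with Control 1 to 4, Mlp37347 1 to 4 and Mlp124499 1 to 4 left out in turn, or without the library named, were as follows. Auxin genes gave 5, 3, 4, 4, 2, 2, 2, 15, 2, 2, 2 and 7 lower. Iron genes gave 4, 3, 3, 7, 2, 2, 2, 10, 2, 3, 2 and 6 higher, and 3 lower without Mlp37347 4. Cold and drought genes gave 4, 3, 3, 4, 1, 1, 1, 24, 2, 3, 2 and 4 lower. Photosynthesis genes gave 4 higher without Mlp37347 4 and 2 higher without Mlp124499 4. Cell cycle genes gave 4 higher without Mlp37347 4.

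Genes changed in 1 line tended to change the same way in the other: 174 were higher in both, 318 lower in both and 5 opposite. MYB51, PBS3 and AT1G61550 were lower in both, AT1G61550 at 5.86 to 10.6 CPM in Control and at most 0.272 CPM in the 8 effector libraries. Independent lists of these sizes would share 9.47 higher and 28.1 lower genes, a comparison that leaves out the common Control. The log2 fold changes correlated across genes, which are not independent replicates, at 0.64, against 0.50 in 20 simulations of unchanged groups with the same Control. Their covariance was 0.342 against 0.0756 simulated. With Control split into separate pairs for the 2 lines (6 arrangements), 44 to 124 genes moved the same way, with correlations of 0.31 to 0.50 and covariances of 0.183 to 0.281. The shared count of 492 was 1024 without Mlp124499 4, 859 without Mlp37347 4 and 171 to 294 without any 1 of Control 1, 2 or 3, Mlp37347 1, 2 or 3 or Mlp124499 1, 2 or 3. It was 164 without Control 1 and Mlp124499 3 and 96 with the mate inner distance as a covariate. The distance was long only in Mlp37347 1, 2 and 3, so that last fit cannot separate it from the line.

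The traditional reference genes did not stand apart in variation from other genes of their expression. The 17 traditional genes had a median CV of 0.294 over the 12 libraries, against 0.302 for matched random lists (two-sided share 0.873). Single genes ranged from 0.147 for UBC9 (AT4G27960), a ubiquitin-conjugating enzyme, to 0.441 for GAPC1 (AT3G04120), a glycolytic enzyme. GAPC1 was at 105 CPM in Control 1 and 255 CPM in Mlp37347 4, and at 550.3 to 589.6 CPM in Mlp37347 1, 2 and 3. The actin gene ACT2 (AT3G18780) had a CV of 0.359. No traditional gene passed the edgeR test in any comparison, where an unadjusted p under 0.05 gave 6 higher in Mlp37347 and 2 higher in Mlp124499 than in Control, and 1 higher and 1 lower between the lines. DESeq2 called 4, 1 and 0 of them, and voom 8 higher and 4 lower, 5 higher, and 6 higher and 4 lower. Without Mlp37347 4, 5 were higher and 1 lower in Mlp37347 by edgeR and 2 lower between the lines. Other libraries left out gave 1 higher in Mlp37347 (without Control 4, Mlp124499 3 or Mlp124499 4) and 2 higher in Mlp124499 (without Mlp124499 4). ACT2 stood at 529 to 567 CPM in Mlp37347 1, 2 and 3, 1670.3 CPM in Mlp37347 4 and 675 to 947 CPM in Control, so that its log2 fold change was -0.53 without Mlp37347 4 and 0.02 with it. As a list they were called higher than Control in both lines (camera adjusted p = 0.0071 and 0.0051; adjusted p = 0.471 and 0.484 with an estimated correlation). Both calls were lost without Control 1 (adjusted p = 0.176 and 0.256), and the first also without Mlp37347 4 (0.0549), within 0.0014 to 0.582 and 5.81e-04 to 0.484 over all alternatives. The 10 tested genes of the array-selected set had a median CV of 0.197 against 0.266 (two-sided share 0.0724), from 0.104 for TIP41L (AT4G34270) to 0.234 for AT4G33380. The share was 0.0094 without Control 1. With CPM by total count it was 0.01, and with TPM 0.0016. It stayed above 0.05 with DESeq2 size factors (0.0912), with genes of at least 10 CPM (0.126) and with CV within groups (0.0626). Without any other single library it was 0.0588 to 0.143. No array-selected gene passed the edgeR or DESeq2 test in any comparison. At an unadjusted edgeR p under 0.05 1 was lower in each line against Control, and voom called 1 higher and 2 lower in each comparison. Without Mlp37347 4, edgeR called 1 higher in Mlp124499 and 1 lower between the lines. The list was not called (camera adjusted p = 0.418 and 0.479 against Control). In each direction 96 genes were chosen for low CV, and medians were averaged over both directions. They had 0.0557 in the libraries used to choose them and 0.158 in the others. There the array-selected set had 0.164, the traditional set 0.297 and all tested genes 0.300. Chosen in libraries 1 and 2, low-CV genes had 0.189 in the others against 0.169 for the array-selected set. The other way round these were 0.127 and 0.159. VPS41 (AT1G08190), a vesicle-sorting protein, had a CV of 0.0428 over all 12 libraries and a mean of 97.3 CPM, and Nek7 (AT3G12200), a kinase, had a CV of 0.0376. Both were chosen on these same libraries.

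**Figure D3:**
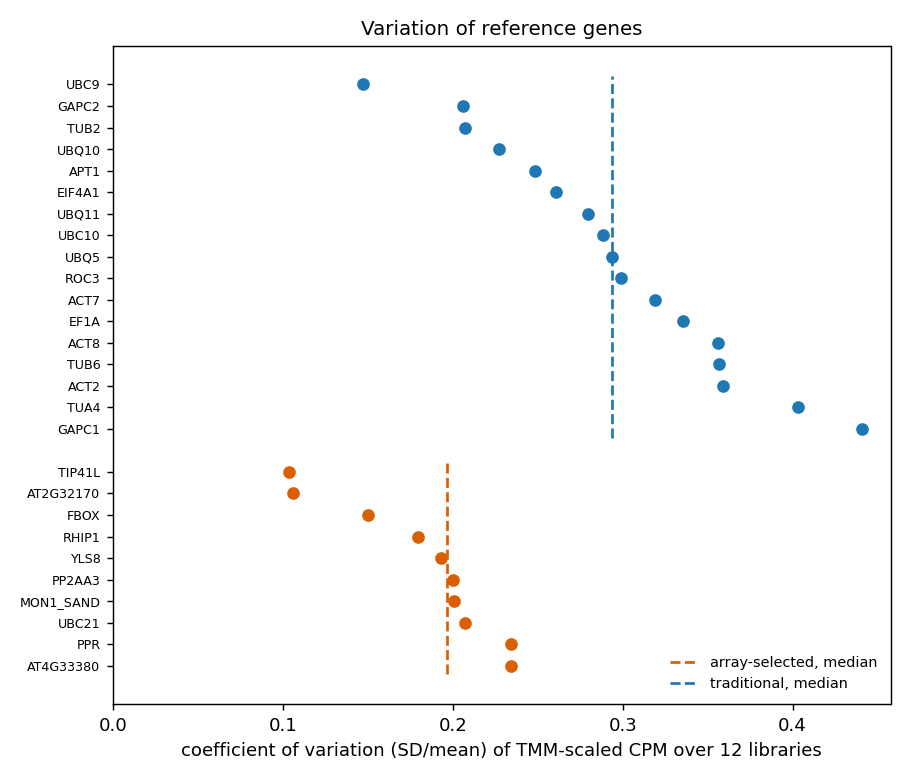
CV of TMM-scaled CPM over the 12 libraries for 10 array-selected and 17 traditional reference genes, with dashed lines at the set medians. The traditional set lay around 0.294 and the array-selected set around 0.197.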

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

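Tests chosen only after the result was seen were those of harvest time on the clock genes, of wrong and swapped labels, of effector action on clock and on immune genes, and of Control 1 and of harvest time on pattern-triggered immunity, and the fits with clock components as covariates were added after seeing the data. Values were compared by the gap between the most extreme library and its nearest neighbour, divided by the range of the group of 4, and chance alone sets apart about 1 in 20 groups. Of 423 groups of named genes 80 were set apart, where about 21.1 would be by chance, and 47 of them by Mlp37347 4. In Mlp37347 4 the ratio singled out AT5G17460 and KIN1 at 0.99, APT1 at 0.98, ACT2, CBF3 and GOLS3 at 0.97, FKF1, PRR3, PDF1.2B and CRT1A at 0.96. The same library stood apart for UBQ11 and AT1G11210 at 0.95, CYP96A5, ACT8, BAK1 and GOLS2 at 0.94, CYCD3;1, CDKB2;1 and MON1_SAND at 0.93, PETE1 and EF1A at 0.92. Further genes set apart by this library were UBQ10, AT4G33380, GI, LNK1 and IMD1 at 0.91, JAZ9 and PIL1 at 0.90, UBC10, PP2AA3 and ERD7 at 0.89, COR15B, GAPC1, TUB6, TUA4, AT1G30470 and COR15A at 0.88. At lower ratios it was set apart by EIF4A1 and DFR at 0.87, PRR5, CBF1 and PAP17 at 0.86, WRKY53, GSTU3 and SYP122 at 0.85, ACT7 and WRKY6 at 0.84. Mlp124499 4 stood apart for AT1G26790 at 0.98, DFR at 0.95, NRT1.8 at 0.93, PRR5 and PRR3 at 0.92, JAZ9 at 0.90, AOC3 at 0.88, FKF1 at 0.87, TUB6 and PIL1 at 0.86, AT5G17460 at 0.85. Control 1 stood apart for AT4G06665 at 0.98, AT2G08915, AT5G22505 and AT2G41105 at 0.97, AT3G16525 and NYE1 at 0.95, PYK10 at 0.86, AT1G56300 and CDKB2;1 at 0.85, UBQ11 at 0.83. Other single libraries were Mlp124499 3 for CRT3 at 0.93, AT4G06665 at 0.91, EIF4A1 at 0.89, GOLS2 at 0.85, Control 4 for FKF1 at 1, CHE and CBF3 at 0.96 and Control 3 for BAK1 at 0.94, VPS41 at 0.84. Mlp37347 1 stood apart for TIP41L at 0.96, Mlp37347 2 for ERF104 at 0.91 and Mlp37347 3 for AT3G16525 at 0.87. Mean list levels set Mlp37347 4 apart for cell cycle at 0.98, glucosinolate and phosphate at 0.96, clock at 0.95, flavonoid and ER folding at 0.93, plasmodesmata at 0.92, photosynthesis at 0.91, iron status at 0.87, auxin response at 0.86, senescence at 0.85. They set Mlp124499 4 apart for clock at 0.90, phosphate at 0.87, Control 1 for photosynthesis at 0.86, clock at 0.84 and Mlp124499 3 for plasmodesmata at 0.86. In sequencing measures Control 1 stood apart in its share of aligned reads (0.86), Mlp37347 4 in mate inner distance (0.89) and Mlp124499 3 in mate inner distance (1, where the other libraries of its group had equal values). The effector lines differed from each other, by the direct camera test, in auxin response (adjusted p = 2.24e-14), cold and drought response (5.30e-13), iron status (4.68e-05), photosynthesis (8.52e-04) and cell cycle (0.0012). With an estimated correlation all 5 calls were lost (adjusted p = 0.205, 0.643, 0.205, 0.712 and 0.712), and 27 of 35 splits of these libraries gave at least 5 lists.

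Clock and cold genes differed within both effector groups, and the clock list varied more among the 4 libraries of each line than matched random lists did (two-sided share 2e-04 in each, the smallest that 10000 lists can give, and 0.834 in Control), which restates the pattern and does not decide on harvest at different times of day. For wrong labels, 150 to 222 genes set Mlp124499 1 to 3 at least 4-fold outside 3 Control libraries. At 11 to 35 of them Mlp124499 4 lay at least 4-fold outside on the same side, and at the rest it did not. The Control library left out gave 0, which argues against a Control library there. For Mlp37347 4 the genes numbered 7 to 9 of 86 to 95 with Mlp124499 1, 2 or 3 left out, where the left-out library gave 0 to 3. With Mlp124499 4 left out they numbered 25 of 239, and Mlp124499 4 itself gave 80. Genes apart numbered 4 as labelled, 3 with Mlp124499 4 in the place of Mlp37347 4 and 0 with Mlp124499 1, 2 or 3. In both counts the highest value came from Mlp124499 4, which itself stood apart from its group, so they do not decide. For a swap of both libraries numbered 4, the 17 genes 4-fold apart after exchange, against 7 as labelled, were 14 against 3 for Mlp124499 1 to 3 with Mlp37347 4 but only 3 against 4 for Mlp37347 1 to 3 with Mlp124499 4, and 0 against 2 genes were wholly absent on one side (AT1G75945 and AT2G01422, seen before that second criterion was set). Mlp124499 4 differed from Mlp37347 1 to 3 in auxin (0.05 against -1.70 to -1.47) and iron genes (0.03 against 1.44 to 1.67). Over all genes its rank correlation with them (0.935 to 0.937) was above that with Mlp124499 1 to 3 (0.911 to 0.928) but below that with Control 2, 3 and 4 (0.950 to 0.957). That of Mlp37347 4 was 0.930 to 0.956 with Mlp124499 1 to 3 and 0.899 to 0.906 with Mlp37347 1 to 3. Of 239 genes 4-fold apart between libraries 1 to 3 of the lines, 98 had both libraries numbered 4 on the exchanged side and 22 on the labelled side. At 100 others only Mlp124499 4 lay on its labelled side, and at 19 only Mlp37347 4 did. A swap, a wrong label of Mlp37347 4, harvest time and an effect of the effector proteins, for which 6 clock members separated all Mlp124499 from all Control libraries and 16 did for Mlp37347, cannot be told apart because the groups hold 4 libraries each and no harvest times are known.

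Immune genes were lower in both effector lines, with 12 salicylic acid members lower in both. Without Control 1, 12 members were lower in Mlp37347 and 11 in Mlp124499, which argues against the low aligned share of that library as the whole cause for these genes. For pattern-triggered immunity 7 and 4 members were lower without Control 1, after 10 and 9. The bound used for salicylic acid, at least 7 members in each line, was thus undecided here. A comparison of levels replaced it after that was seen. In it all 8 effector libraries (-1.31 to -0.85) lay below Control 2, 3 and 4 (-0.39 to 0.21). The median log2 fold changes went from -0.61 and -1.10 to -0.53 and -1.05. These shifts were less than the median SE of single members (0.36 in each line), a wide bound for a list median that decides little. These levels argue against Control 1 as the whole cause for this list too. With the first components of the clock list as covariates, 2 salicylic acid members were lower in each line, which meets the bound set for a harvest-time cause before that count was seen, and 2 and 6 of pattern-triggered immunity. The median log2 fold changes went from -2.10 to -1.96 and from -1.53 to -1.31 for salicylic acid, with the median SE up from 0.39 to 0.69 and from 0.38 to 0.57, and to -0.40 and -0.86 for pattern-triggered immunity (SE from 0.33 to 0.43 and 0.33 to 0.35), so the salicylic acid calls ended mainly through lost precision, and the verdict was set to undecided only after that was seen. Each construct made up 1 group, so any other difference between the plants of the groups went with it and cannot be separated from the effectors. Harvest time and an effect of the effectors cannot be told apart here, since the clock components differ between the groups for all effector libraries but Mlp124499 4. Its first clock component (-6.94) lay within the Control range of -8.53 to -6.72. Its salicylic acid mean (-1.37) and pattern-triggered immunity mean (-0.92) still lay below every Control library (lowest -0.97 and -0.39), but 1 library does not decide.

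Control 1 and Mlp124499 3 deviated from their groups together, with a correlation of 0.55 across genes. Across genes their deviations correlated with exon length at 0.15 and 0.0515 and with GC content at -0.0619 and -0.0964 (Spearman), values too weak for either bias as the cause. No biological explanation was tested, and they had the lowest shares of aligned reads, 57.6% and 88.0%.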

How the results depend on the processing

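The alternatives without both libraries numbered 4, without Control 1 and Mlp124499 3, with clock components and with inner distance, and leaving out libraries for the lists, were chosen after seeing the data. The cause of a shift was not tested except where fewer libraries or a stricter threshold makes it plain. Under the settings fixed beforehand other than leaving out a library, 2399 values of named genes kept direction and side of the threshold, 275 lost and 82 gained a call, 97 without a call changed sign and 1 turned. With 1 library left out 2389 kept, 384 lost, 34 gained, 84 changed sign without a call and 1 turned. Of list values, 148 kept, 40 lost and 1 changed sign under the settings fixed beforehand. With the group size of these data 2-fold changes were recovered in 6% to 21% of simulated cases.

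Genes higher and lower in Mlp37347 against Control, in Mlp124499 against Control and between the lines, then shared genes, were as follows. Total-count scaling gave 351 and 1900, and 126 and 545 between the lines. Scaling by traditional references gave 193 and 1719, then 130 higher, then 64 and 137, and array-selected references 388 higher in Mlp37347. DESeq2 gave 1341 higher, then 645 and 853, then 687 and 684, with 862 shared. Voom with weights gave 5262 and 5636, 3068 and 3841, 5221 and 5149, with 3892 shared. Only the 8 libraries compared gave 51 and 105 between the lines. An adjusted p under 0.01 gave 143 and 323, 69 and 156, 45 and 72, with 116 shared, and a tested fold of 1.5 gave 121 and 333, 84 and 151, 29 and 68, with 127 shared. Without both libraries numbered 4 the counts were 3177 and 3066, 1728 and 2013, 2491 and 2490, with 1837 shared. Without Control 1 and Mlp124499 3 they were 88 and 165 for Mlp124499, 113 higher between the lines and 164 shared. Clock components gave 318 and 577, 638 and 982, 1022 and 1065, and inner distance 172 and 106, then 490 higher, then 78 lower between the lines, with 96 shared. Neither covariate is free of the groups. The first clock component was -8.53 to -6.72 in Control and Mlp124499 4 and 3.09 to 7.51 in the other effector libraries. The distance was 110 to 115 bp in Mlp37347 1, 2 and 3 only. Shifts under these covariates therefore do not show a cause.

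The replicate block gave 236 and 566, 96 and 225, 53 and 103, with 191 shared, and 26 list calls. The numbers do not pair the libraries: 0 of 12 same-number pairs had a correlation of deviations over 0.1 (-0.39 to 0.09), and 0 of 12 libraries were closest to their own number.

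Leaving out 1 library at a time gave 222 to 2245 genes higher and 401 to 2158 lower in Mlp37347, 89 to 793 and 148 to 1085 in Mlp124499, 62 to 1407 and 87 to 1395 between the lines, and 171 to 1024 shared. The median CV of traditional genes ranged from 0.255 to 0.314 and that of array-selected genes from 0.160 to 0.210. CPM by total count gave 0.173 for array-selected genes, TPM 0.164 for these and 0.286 for traditional genes, and CV within groups 0.266 for traditional genes. List calls numbered 27, of which 1 held with an estimated correlation, and fry gave 14.

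Direction turned for ACT2 in Mlp37347 with voom (-0.62), without Mlp37347 4 (-0.53) and without both libraries numbered 4 (-0.53). With 1 library left out it ranged from -0.53 to 0.23. Clock components turned FKF1 (-0.10), PRR3 (-0.93), ELF4 (-0.38), AT1G26790 (0.19), COR15B (-1.26) and BHLH101 (-1.65) in Mlp37347, and inner distance turned DFR between the lines (-0.69). FKF1, PRR3 and ELF4 belong to the list that gave the components, so that fit takes out much of their own change. Glucosinolate genes turned to higher in Mlp37347 without Mlp37347 4 (adjusted p = 1.71e-04) and without both numbered 4 (2.41e-05). With clock components, lists that turned were cold and drought (0.0123), heat shock (0.650) and touch (0.616) in Mlp37347, glucosinolate (5.39e-06), flavonoid (0.0168), auxin (0.667) and heat shock (0.302) in Mlp124499, and glucosinolate (4.73e-09) and cell cycle (0.775) between the lines. With inner distance they were flavonoid (3.82e-05), cell cycle (0.489) and senescence (0.712) in Mlp37347, and photosynthesis (0.594), clock (0.0141), glucosinolate (2.90e-06), flavonoid (0.0065), cell cycle (0.0782) and senescence (0.0188) between the lines.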

Other observations

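Secondary metabolism genes set single libraries apart without a list call against Control. Glucosinolate synthesis genes had mean levels of 0.71 to 0.87 (log2, against the Control mean) in Mlp37347 1, 2 and 3 and -2.70 in Mlp37347 4, and -0.92 to -0.62 in Mlp124499 1, 2 and 3 and 0.44 in Mlp124499 4. IMD1, an enzyme of glucosinolate chain elongation, stood at 246 to 271 CPM in Mlp37347 1, 2 and 3 and at 5.94 CPM in Mlp37347 4. The anthocyanin gene DFR stood at 46.6 to 53.7 CPM in Mlp37347 1, 2 and 3, 0.266 CPM in Mlp37347 4 and 0.738 to 4.73 CPM in Mlp124499.

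GOLS3, a galactinol synthase gene, stood at 46.0 to 63.3 CPM in Mlp124499 1, 2 and 3, 19.2 CPM in Mlp124499 4, 16.6 CPM in Mlp37347 4 and at most 2.93 CPM in Control and the other Mlp37347 libraries. WRKY18, a defence regulator, stood at 56.2 to 71.5 CPM in Mlp37347 1, 2 and 3, above the Control range of 13.6 to 26.55 CPM, and at 10.7 CPM in Mlp37347 4.

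Other splits of the same libraries were counted, with the prediction set beforehand. For Mlp37347 against Control 1 of 35 splits, the real one, gave as many as 1644 genes (highest other 902), and for Mlp124499 1 of 35 gave 815 (highest other 401). Both met the bound set beforehand, a share under 0.05, where 1 of 35 is the smallest share possible. This argues against a random division of the libraries as the source of these counts. A batch or harvest difference between the groups would give the same result. For the lines against each other 2 of 35 splits gave at least 513, and the split with the libraries numbered 4 exchanged gave 3815, a structure of the samples, so chance cannot be excluded by this count. For shared genes 1 of 50 splits gave 492 (highest other 0), but 0 of the 49 others had changed genes in both comparisons, so the count bears on the calls and not on how far they overlap. Chance was not excluded for the list calls: 20 of 35 splits gave at least the 10 lists called in Mlp37347 (highest other 16), 3 of 35 the 12 in Mlp124499 (highest other 12) and 27 of 35 the 5 between the lines (highest other 10).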
